A study of Mus musculus with 6 samples.

How the data were processed

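Genomic DNA of 3 polyps and of normal small intestine of ApcΔ716 mice was extracted, fragmented, amplified and labelled with Cy3 or Cy5, per the labels' protocols and the series' design text. Each polyp was hybridised against normal DNA in both dye orientations on Agilent mouse arrays. Per the file headers, 5 arrays were read with Agilent Feature Extraction 11.5.1.1 and 1, polyp 1 in Cy3, with version 12.0.3.1. That array was also the only one scanned on another day, so this batch holds 1 array and could not be tested as one. Probe positions are on mm9, per the file headers.

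The deposited intensity values are spot signals per channel. Per the file headers, the processed intensity was background-subtracted, spatially detrended and scaled by a linear dye factor per channel. The deposited log10 ratio is that of red over green processed signal, not turned for the dye swap, and it matched the processed signals within 0.001 for at least 99.9% of probes on each array. The deposited scanner files also hold flags of 0 or 1 per spot. A table of log2 ratios made by the authors covers 793188 probes. Set against the scanner values, its columns correlated at 0.940 to 0.971 with red over green on the arrays with the polyp in Cy5, and at -0.939 to -0.970 on the dye swaps. Slopes were 0.878 to 0.940 on the former and -0.939 to -0.877 on the latter. Its scale is therefore log2 and its direction polyp over normal on all arrays. Its column medians were 0.0084 to 0.017, and how the authors normalised it is not given in the sources used here.

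For the main values, the log2 ratio of processed red over green signal was turned to polyp over normal. Control spots and between 125 and 329 outlier spots per array were left out, spots of a probe were averaged, and each array was centred on its autosomal median. No loess was applied. The 2 dye orientations of a polyp were then averaged. The SD of the log2 ratio between neighbouring probes, as the scanner software reports it, was 0.165 to 0.200 per array.

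Medians over windows of 1 Mb with at least 20 probes, and over chromosomes, were tested against 0 with an intercept fit and empirical Bayes moderation in limma 3.58.1 under R 4.3.3, two-sided, with Benjamini-Hochberg adjustment at 0.05. Segments were found in each polyp by a piecewise-constant fit (PELT) with a penalty of 10 times the probe variance times the natural log of the number of probes. A segment was called at a mean of at least 0.2 in size over at least 10 probes, with the same sign and at least 0.1 in size in both dye orientations. Segments have no p. Scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and numba 0.67.0, and figures were drawn with matplotlib 3.10.9.

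The window fit was tested on 2536 simulated windows, with independent noise of the spread it had pooled over the real windows. It recovered 12% of changes of 0.02, 96% of changes of 0.05 and 100% of those of 0.1 and 0.2 in log2 ratio, with 5 false calls. The simulation had no regional profile and the same spread in every window, so these rates hold only under the assumptions of the fit. The segmentation was tested on 3 simulated profiles of 963261 probes, which were flat apart from the added segments and so lack the regional profile of the real arrays. At the threshold of 0.2 it recovered 96.7% of changes of 0.66 over 10 probes, 38.3% of changes of 0.33 over 30 probes and 88.3% of changes of 0.22 over 100 probes, with 0 false calls. It recovered 0% of changes of 0.33 over 10 probes and of 0.22 over 10 or 30 probes, so changes of that kind would be missed.

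The groups, tests, gene lists and rules for named items, as well as most alternatives, were fixed before the data were examined. The named windows are the 5 largest in each direction among those past the threshold with the same sign on all 6 arrays. The alternatives were normexp on the median spot and background signals (offset 50), loess, the authors' table, centring on the mode, each dye orientation alone, probes well above background only, windows of 500 kb and 5 Mb, a random block for polyp, a trended and robust fit, a minimum size, other segment thresholds and penalties, and leaving out each polyp.

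After seeing the data, each polyp was also compared with the other 2 polyps. For segments, a running median over 101 probes of their mean, scaled by a line fitted over the autosomes, was subtracted, and segments of at least 0.1 in size with at least 0.05 in both dyes were called. For chromosomes, the line was fitted on 1 Mb windows of the other autosomes. Signals were further compared 1 dye at a time between arrays, polyp with polyp and normal with normal. Shares of cells assume that the remaining cells have 2 copies.

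The scanner files give positions and no gene names, and the gene table used, of assembly GRCm38.p6, differs in build from the probes. It was used only for names, for the chromosome of a gene and for counts of protein-coding genes per chromosome. Some members of the gene lists are not reported here by name. Tests per gene, tests of gene lists, the lymphocyte receptor loci, families of copy-number-variable genes and a correction for GC content were planned and not run for this reason.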

Results

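Copy number was measured in 3 independent small intestinal polyps of ApcΔ716 mice aged 16 weeks. These mice carry a truncated allele of Apc, a tumour suppressor that restrains Wnt signalling, and develop intestinal polyps. The labels place the question in somatic copy number alterations, that is, gains and losses of DNA acquired in the tumour. DNA of each polyp was hybridised together with DNA of normal small intestine to a comparative genomic hybridisation array, on which the ratio of the 2 dyes at a probe reports the ratio of copies. Each polyp was measured on 2 arrays with the dyes exchanged, which gave 6 arrays. The 2 arrays of a polyp hold the same DNAs and were counted as 1 replicate, so n = 3 polyps. Each array carried 963261 distinct mapped probes at a median spacing of 1783 bp, positions being on mm9. Between 98.3% and 99.4% of the spots were well above background in both channels. All log2 ratios below are polyp over normal, and the number of arrays limits their precision.

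The first comparison asks whether whole chromosomes were gained or lost in the polyps. No autosome was close to the loss or gain of 1 copy in all cells, which would give log2 ratios of -1.0 and 0.58. Over the 19 autosomes and 3 polyps, the chromosome medians lay between -0.029, on chromosome 3 of polyp 3, and 0.041, on chromosome 11 of polyp 1. Read as a change of 1 copy in a share of cells, these extremes correspond to 4.0% and 5.7% of cells. Chromosome 18, which carries Apc together with Smad4, Smad2 and Dcc, had a mean log2 ratio of -0.012 ± 0.0043 (SD, n = 3), with -0.0072, -0.012 and -0.016 in polyps 1, 2 and 3. The array counts copies and does not tell which allele is present.

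Small shifts were shared by the polyps. With limma and Benjamini-Hochberg adjustment, 6 of 21 chromosomes were higher and 9 were lower than the array median. Chromosome 11, home of Trp53, the gene of the p53 tumour suppressor, and of Axin2, a negative regulator of Wnt signalling, was the highest at 0.034 ± 0.011 (SD, n = 3). Chromosome 7 followed at 0.023 ± 0.0042. The lowest autosome was chromosome 3, with Fbxw7 and Nras, at -0.024 ± 0.0072 (SD, n = 3). The shift of chromosome 18 had an adjusted p of 0.0097 in limma, with the same sign on all 6 arrays. It missed the threshold without polyp 3, at -0.0094 (adjusted p 0.11), and with each array centred on the mode of its ratios in place of the median, at -0.0032 (adjusted p 0.43). Without polyp 3, 5 chromosomes were lower. Exact sign-flip tests cannot go below p = 0.25 with 3 polyps. The tests compare the ratios with 0 and leave out the spread of the normal DNA, which was the only reference. Mode centring gave 7 higher and 2 lower chromosomes. In the authors' deposited ratios limma called 0 in each direction, with 0 at an unadjusted p under 0.05, and chromosome 18 stood at -0.0050 (adjusted p 0.31).

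Chromosomes X and Y showed no sign that polyp and normal DNA came from animals of different sex. X had a mean log2 ratio of -0.034 ± 0.0018 (SD, n = 3), which was 0.0069 in the authors' deposited ratios, and Y of -0.026 ± 0.015, both far from the values near 1 or -1 that X would take in a mismatch. The Y value rests on 492 probes.

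The gene lists fixed before the data were examined could be placed by chromosome only, and the values that follow belong to whole chromosomes and not to the genes. Of 14 genes of the Wnt pathway, 7 lie on chromosomes that were higher, among them Ctnnb1, which encodes beta-catenin, on chromosome 9 at 0.0084. Another 6 lie on lower chromosomes, such as Lgr5, a marker of intestinal stem cells, on chromosome 10 at -0.011 (0.0023 in the authors' deposited ratios), and 1, Tcf7l2, lies on chromosome 19, which did not pass the test. Of 17 colorectal tumour suppressors, 7 lie on higher, 5 on lower and 5 on other chromosomes. Rb1, on chromosome 14 at -0.0034, belongs to the last group. Of 25 oncogenes, 8 lie on higher chromosomes and 9 on lower ones, including Braf on chromosome 6 at -0.013. Myc lies on chromosome 15, which stood at 0.0013 ± 0.0051 (SD, n = 3). Of 16 DNA repair genes, 14 lie on higher chromosomes, for example Msh6 on chromosome 17 at 0.015. Of 14 chromosome segregation genes, 6 lie on higher and 5 on lower chromosomes. Of 12 large or fragile-site genes, 2 lie on higher and 4 on lower chromosomes. Of 8 genes at loci that vary in copy number between mice, 3 lie on higher chromosomes and 1 on a lower one. No chromosome mean behind these counts exceeded 0.034 in size. The counts were not set against the share of all genes on the same chromosomes, so none of them is read as an excess. The counts rest on calls that 1 polyp or the centring can decide. With mode centring, 7 of the 9 lower chromosomes missed the threshold, namely 1, 6 (-0.0042), 10 (-0.0024), 13, 16, 18 and Y, and chromosome 8 newly passed it as higher. Without polyp 3, chromosomes 5, 6, 9, 10, 13, 16 and 18 missed the threshold and chromosome 14 passed it. Chromosome 9 also missed it without polyp 1 (0.0070), with normexp signals (0.0062) and in the authors' deposited ratios (0.0003), where no chromosome passed.

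The second comparison looked along the chromosomes in windows of 1 Mb. Regional differences of small size were present on the autosomes and X, and their profiles were similar in the 3 polyps. In limma, 708 of 2536 windows were higher and 1253 were lower than 0 at an adjusted p under 0.05, and 1954 windows had the same sign on all 6 arrays. That is 77.1% of windows. Every ratio has normal DNA as its reference, and the labels do not say whether it was the same DNA on all arrays. A feature of a shared normal DNA alone would give the same likeness between polyps, so the likeness does not tell which of the DNAs differs. With a minimum size of 0.1, 141 windows were higher and 19 lower. The 19 became 47, 46 and 6 without polyps 1, 2 and 3, 101 and 7 with the polyp in Cy5 or in Cy3 alone, and 1 with mode centring. With normexp signals, limma gave 3 higher and 0 lower windows at this size, with 1777 at an unadjusted p under 0.05. Chromosome 4 held 23 of the 141, chromosome 5 held 20 and chromosome 7 held 16.

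The 5 highest windows lay on chromosome 10 from 80000001 to 81000000 (0.22 ± 0.030, SD, n = 3) and from 79000001 to 80000000 (0.20 ± 0.039), on chromosome 4 from 140000001 to 141000000 (0.19 ± 0.038), on chromosome 8 from 122000001 to 123000000 (0.17 ± 0.032) and on chromosome 17 from 27000001 to 28000000 (0.17 ± 0.023). The 5 lowest were on chromosome 1 from 143000001 to 144000000 (-0.11 ± 0.0071), chromosome 8 from 51000001 to 52000000 (-0.11 ± 0.021), chromosome 2 from 40000001 to 41000000 (-0.11 ± 0.0034), chromosome 3 from 71000001 to 72000000 (-0.11 ± 0.0069) and chromosome 16 from 67000001 to 68000000 (-0.11 ± 0.018). On chromosome 18, 16 of 88 windows were higher and 45 lower, and no polyp had a window outside -0.12 to 0.11. The standard error of limma was 0.0096 in each of the 10 named windows, because its fit pooled the spread over all windows. In the authors' deposited ratios, limma called 288 windows higher and 294 lower of 2058, with 808 at an unadjusted p under 0.05, and 0 of the called windows reached a size of 0.1.

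**Figure D1:**
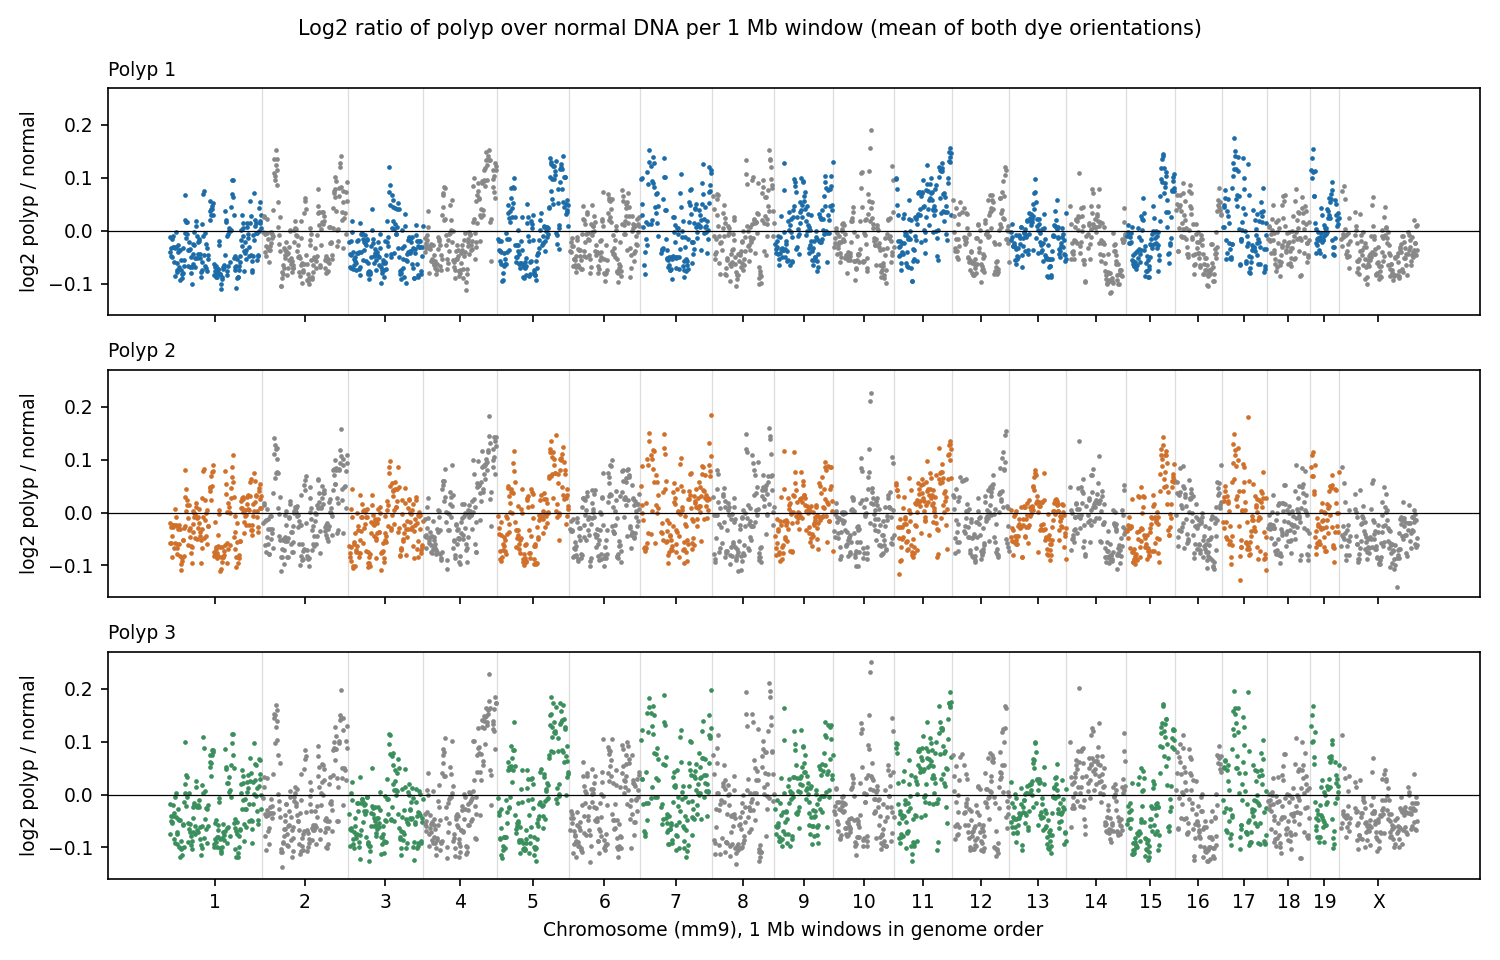
Log2 ratio of polyp over normal DNA (vertical axis) in windows of 1 Mb along chromosomes 1 to 19 and X (horizontal axis, mm9), with 1 panel per polyp and 1 point per window, colour alternating by chromosome. The peaks and troughs fall at the same places in the 3 polyps, and no chromosome stands near -1.0 or 0.58.

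Across autosomal windows, the 2 dye orientations of a polyp correlated at r = 0.931 to 0.961 after the sign was turned, and arrays of different polyps at r = 0.875 to 0.943. Across single probes, r between the dye orientations of a polyp was 0.076 to 0.109, below the 0.235 to 0.341 between different polyps labelled with the same dye. Windows and probes are not independent replicates.

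The third comparison asked which segments were gained or lost in each polyp. In polyp 1, 1 segment was called, and it was a loss. Polyp 2 had 8 called segments and polyp 3 had 11, all of them higher than normal. No called segment lay on chromosome 18, although lowering the threshold from 0.2 to 0.1 gave 2 there in polyp 2 and 2 in polyp 3. Short changes of the sizes that the simulation did not recover would be missed there. The called loss, on chromosome 8 from 111455143 to 111471915, covered 13 probes at a mean log2 ratio of -0.58 ± 0.063 (SE over probes). Of the 20 called segments, the other 19 had the same sign in all 3 polyps and reached 0.1 in each. None of these 19 was called again when each polyp was set against the other 2 polyps, as described below. They follow the regional profile that the polyps share and are not shown to be gains particular to a polyp.

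Among the segments of polyp 3, the longest ran on chromosome 8 from 121899923 to 125417773, with a log2 ratio of 0.21 in polyp 3 and of 0.16 in polyps 1 and 2. A segment on chromosome 10 was called in both polyp 2, from 78955906 to 81090151 at 0.23, and polyp 3, from 78987714 to 81109088 at 0.25. The same stretch stood at 0.18 in polyp 1. In all, 4 pairs of segments were shared between polyps at a reciprocal overlap of 50%. As a background, the difference between the dye orientations divided by 2, in which copy number cancels, gave 2, 0 and 1 calls in polyps 1, 2 and 3. Being a single profile, it did not have to pass the rule for both dye orientations. The regional profile that the polyps share also largely cancels in it. The background calls are therefore not a rate of false calls for the called segments. Counts depend on the settings. The threshold of 0.1 gave 44, 76 and 123 segments, and normexp signals, whose offset draws ratios toward 0, gave 0 in each polyp. In the authors' deposited ratios there were 3, 1 and 1 segments and 0 shared pairs. A halved penalty gave 6, 50 and 57 segments and 14 shared pairs.

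Differences between the polyps were examined next, in a comparison chosen after seeing the data. Each polyp was set against the scaled mean of the other 2 polyps, which removes the profile they share. Chromosome 14 of polyp 3 stood out. Its median relative log2 ratio was 0.039, with all 115 windows of the chromosome above 0. The value was 0.041 with the polyp in Cy5, 0.035 with the polyp in Cy3 and 0.029 with normexp signals. Read as 1 extra copy in a share of cells, the value of 0.039 corresponds to 5.5% of cells. This share takes the other 2 polyps as its baseline, and not normal DNA. Against normal DNA, chromosome 14 had a log2 ratio of 0.018 in polyp 3 and of -0.018 and -0.010 in polyps 1 and 2. The 54 values of the other autosomes in the 3 polyps had an SD of 0.0062, and the largest in size was 0.021, on chromosome 19 of polyp 1. Rb1, Bmpr1a, Klf5 and Fhit lie on chromosome 14. As 1 polyp is concerned, the difference has no biological replicate.

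**Figure D2:**
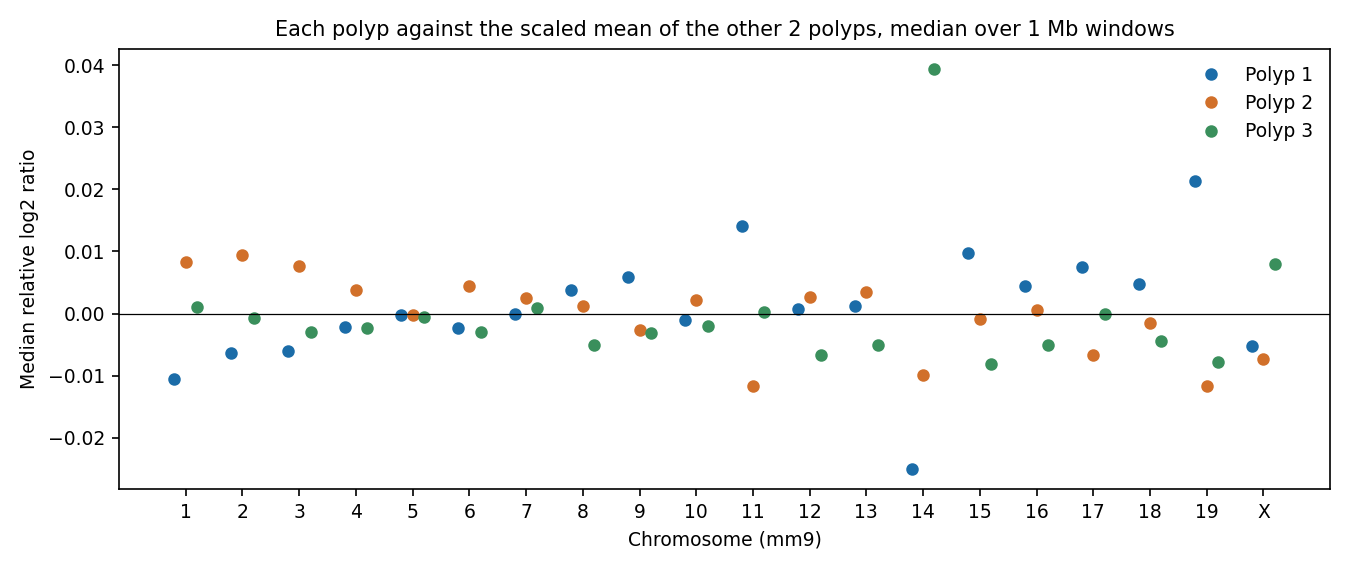
Median relative log2 ratio of each polyp against the scaled mean of the other 2 polyps (vertical axis) by chromosome (horizontal axis, mm9), with 1 point per polyp and chromosome. Chromosome 14 of polyp 3 lies at 0.039, and polyp 1, whose reference includes polyp 3, lies at -0.025 there.

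At a finer scale, the same comparison called 3 segments in polyp 1, 3 in polyp 2 and 1 in polyp 3. At a size of 0.1, the background from the difference between the dye orientations gave 2, 1 and 2 calls. As a single profile, that background did not have to pass in each dye, and the shared profile largely cancels in it without being subtracted. Its calls are therefore not a rate of false calls for the segments found here. With normexp signals the comparison with the other polyps called 0 in each polyp. The intervals described here were chosen after their values were seen. On chromosome 8 from 111455143 to 111471915, the log2 ratio against normal was -0.58 ± 0.063 in polyp 1, 0.39 ± 0.056 in polyp 2 and -0.083 ± 0.061 in polyp 3 (SE over 13 probes). On chromosome 2 from 122204056 to 122221259, it was -0.58 ± 0.11, 0.36 ± 0.070 and -0.29 ± 0.057 (SE over 10 probes). Normexp signals gave -0.28, 0.29 and -0.079 at the first and -0.27, 0.21 and -0.13 at the second, in polyps 1, 2 and 3. The authors' deposited ratios gave -0.66, 0.28 and -0.20, and -0.61, 0.32 and -0.33. The order of the polyps was the same in both dye orientations at both intervals. In polyp 2, the called segment at the first of these was wider, from 111370198 to 111486858. Over its 76 probes the log2 ratio against normal was 0.19 in polyp 2 and -0.11 in polyp 1.

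On chromosome 8 from 120825423 to 121313544, polyp 3 alone was lower. Its log2 ratio was -0.11 ± 0.0089 (SE over 299 probes), against 0.012 ± 0.0079 in polyp 1 and 0.0064 ± 0.0075 in polyp 2. It was -0.083 with normexp signals and -0.16 in the authors' deposited ratios, where polyps 1 and 2 stood at -0.0165 and -0.033. The dye orientations of polyp 3 gave -0.11 each, and the ratio corresponds to loss of 1 copy in 14.9% of cells. Relative to the other polyps the interval stood at -0.13, while the lowest run of as many probes elsewhere on the autosomes of polyp 3, on chromosome 15, reached -0.063. By size, the largest other run was higher, at 0.082 on chromosome 4. The interval was itself picked as the called segment of polyp 3 in this comparison. Its larger size than other runs follows from that choice and adds no support. On chromosome 11 from 3030764 to 3156015, polyp 2 had a log2 ratio of -0.060, against 0.18 and 0.16 in polyps 1 and 3. The other 2 segments lay on chromosome 4, from 112773092 to 112895989 in polyp 1 and from 111962345 to 112065411 in polyp 2. There the relative values differed widely between the dyes, at 0.69 and 0.063 in the first and -0.14 and -0.81 in the second.

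**Figure D3:**
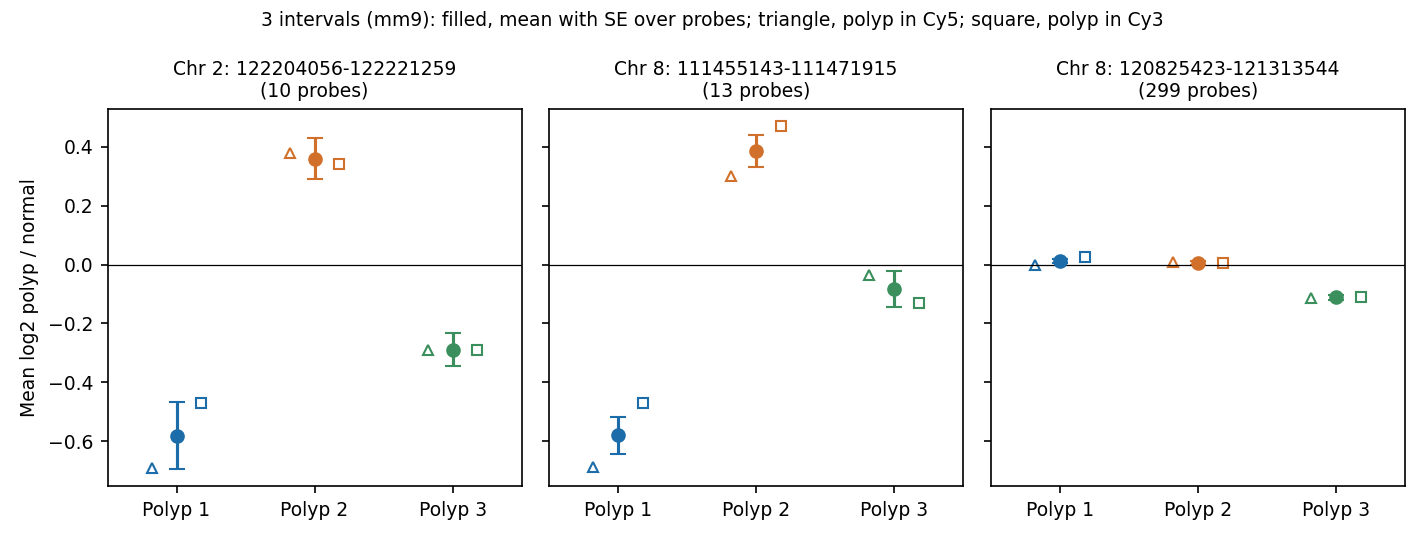
Mean log2 ratio of polyp over normal DNA (vertical axis) at 3 intervals in each polyp (horizontal axis). Filled points are means of both dye orientations with the SE over probes, triangles the arrays with the polyp in Cy5 and squares those with the polyp in Cy3. Polyps 1 and 2 lie on opposite sides of 0 at the intervals on chromosome 2 and, with 13 probes, on chromosome 8, and polyp 3 lies at -0.11 in the interval with 299 probes.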

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

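The comparisons of a polyp with the other 2 polyps were chosen after seeing the data, and the other settings before; where a value changed, the cause was not tested unless a reason is given. Counts of higher and lower 1 Mb windows, 708 and 1253, stayed within 1.5 times under normexp, loess, mode centring, probes well above background, each dye alone, a random block for polyp and the trended robust fit, and lay at 631 to 673 and 1130 to 1206 with 1 polyp left out. They were 288 and 294 in the authors' table, 141 and 19 with a minimum size of 0.1, 1307 and 2447 with windows of 500 kb, and 171 and 270 with windows of 5 Mb, where the number of windows differs. Chromosome counts, 6 higher and 9 lower, became 0 and 0 in the authors' table, and 2 lower with mode centring. With 1 polyp left out they ranged from 4 to 7 and from 5 to 9, the 5 being without polyp 3. Chromosome 18 (-0.012) missed the limma threshold at -0.0050 in the authors' table, at -0.0032 with mode centring and at -0.0094 without polyp 3, and ranged from -0.014 to -0.0094 with 1 polyp left out. Of 199 alternative values of the other 20 chromosomes, 25 missed the threshold with their sign kept, 3 newly passed it, and 2 of chromosomes that had passed it missed it and changed sign as well, both in the authors' table: chromosome 10 at 0.0023 and X at 0.0069. Chromosomes 2, 12, 14, 15 and 19, which had not passed it, changed sign in at least 1 alternative. The 10 named windows kept their sign in all 69 alternative values, but 30 of these moved by 1 SD or more: 10 with normexp, 9 in the authors' table, 3 each with mode centring and with either dye alone, and 2 with loess. The highest, on chromosome 10 from 80000001 (0.22), was 0.12 with normexp and 0.085 in the authors' table. The lowest, on chromosome 1 from 143000001 (-0.11), was -0.070 and -0.014. The log2 ratios at the 3 intervals kept their sign where they stood clear of 0 in the main values, but 11 of 63 alternative values were counted as moved, 6 with normexp and 5 in the authors' table. The bound of this count was wider than the SE over probes. Polyp 1 at the short interval on chromosome 8 (-0.58 ± 0.063) was -0.69 in Cy5 alone and was not counted. With normexp, polyp 1 (-0.58 at both short intervals) stood at -0.27 on chromosome 2 and -0.28 on chromosome 8. Polyp 3 at the long interval on chromosome 8 (-0.11) stood at -0.083 with normexp and -0.16 in the authors' table.

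Called segments in polyps 1, 2 and 3 (1, 8 and 11) numbered 0, 0 and 0 with normexp, and 3, 1 and 1 in the authors' table. With loess there were 3 in polyp 1 and 5 in polyp 3, and with mode centring 2 in polyp 1. The arrays with the polyp in Cy5 alone gave 4 in polyp 1 and 2 in polyp 2, and those in Cy3 alone 0 in polyp 1 and 4 in polyp 3. A threshold of 0.1 gave 44, 76 and 123, and one of 0.4 gave 0 in polyps 2 and 3. At least 5 probes gave 2 in polyp 1, and at least 20 gave 0 there. A halved penalty (multiplier 5) gave 6, 50 and 57, and a doubled one 0, 1 and 7. Shared pairs, 4 in the main setting, were 0 with normexp, in the authors' table and at a threshold of 0.4, 1 with the polyp in Cy3 alone and with the doubled penalty, 14 with the halved penalty and 113 at a threshold of 0.1. Segments against the other 2 polyps, 3, 3 and 1, were 0, 0 and 0 with normexp, 1 in polyp 2 in the authors' table, and 1 in polyp 1 with probes well above background. Chromosome 14 of polyp 3 (0.039) was 0.029 with normexp, 0.032 without polyp 1 and 0.045 without polyp 2 as reference. With normexp, 3 windows were higher and 0 lower at a size of 0.1 or more. At least 98.3% of spots were well above background on each array, but whether signal strength limited precision was not tested. No paired analysis was possible because a single group was compared with 0. Tests per gene and per gene list, the lymphocyte receptor loci and the GC correction were not run.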

Other observations

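The relation with gene content and the tests below were chosen after the result was seen, except the 2 tests within 1 Mb windows, and even there the relation of whole windows with probe brightness had been seen. Gene-rich chromosomes had higher ratios in the polyps. Across the 19 autosomes, the number of protein-coding genes per Mb (gene counts of GRCm38.p6 over the span of the mm9 probes) correlated with the mean log2 ratio at Pearson's r = 0.858 and Spearman's rho = 0.854, each with a two-sided permutation p of 2e-05. The one-sided p was doubled, and 2e-05 is the smallest value that 100000 permutations can then give. Gene-rich chromosomes 11 and 7, at 13.5 and 13.6 genes per Mb, had the highest means, 0.034 and 0.023. Without these 2 chromosomes, the farthest from the median in gene content, r was 0.752. It was 0.797 to 0.844 in single polyps and 0.542 in the authors' deposited ratios. This was the only relation across chromosomes that was computed, and chromosomes are not independent replicates. Chromosome 14 of polyp 3 is part of these values. Across 2385 autosomal windows, the ratio also rose with the number of probes per window, at rho = 0.565, 0.627 and 0.582 in polyps 1, 2 and 3. Probe density was not separated from gene content.

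The regional profile shared by the 3 polyps had a window SD of 0.056, 0.055 and 0.070 in polyps 1, 2 and 3, but of 0.029, 0.018 and 0.030 in the authors' deposited ratios, where r between polyps was 0.451 to 0.791. Uneven hybridisation is argued against by normal DNA compared with normal DNA between arrays in 1 dye, whose window SD was at most 0.0255 while that of polyp against normal was at least 0.0433, and dye bias by r = 0.931 or more between the dye orientations. A larger share of replicating cells in polyps, which would raise early-replicating and mostly gene-rich regions, may contribute: as the whole cause it called for under 10% of the covariance between polyps to lie within 1 Mb windows and would be excluded above 25% in each pair, and the shares were 22.9% to 29.0%. Recovery or amplification of DNA that depends on base composition may also contribute, since within windows the ratio fell with probe brightness at a rho of -0.287 to -0.251, between the bounds of 0.1 and 0.3 in size, and across whole 1 Mb windows rho was -0.669 to -0.617 with the brightness averaged over the 6 arrays. These 2 explanations cannot be told apart here, because both tests fell between their bounds and base composition itself was not measured, and a feature of the normal DNA alone, if it was the same on all arrays, would also give a shared profile and was not tested.

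Chromosome 14 of polyp 3 stood 0.039 above the other polyps. The medians of 2156 other, overlapping runs of as many windows in polyp 3 reached at most 0.0088 in size. Chromosome 14 was picked as the largest value after the other chromosomes had been seen. These runs therefore show how far it stood from the rest of polyp 3 and do not test the shared profile as its source. A deviating hybridisation of the normal DNA is argued against by normal signals that differed by at most 0.0035 on this chromosome in 1 dye at a time, while polyp 3 exceeded the other polyps by 0.034 to 0.035 in each of 4 such comparisons. A candidate explanation is a gain of the whole chromosome in a small share of cells. Of 5 equal parts of the chromosome, the lowest had 0.75 of the median of the highest, 0.034 against 0.045, above the bound of 0.7. That bound was set after values along the chromosome had been seen, so passing it lends the gain no independent support. The gain remains a hypothesis, found in 1 polyp, and whether the cells were tumour cells was not tested.

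The short intervals on chromosomes 2 and 8 differed between polyps although the labels give 1 inbred background, C57BL/6J. A different normal DNA on each array is argued against by normal signals that differed by at most 0.1777 there in 1 dye, while polyps differed by 0.32 to 1.11. On chromosome 8, whole copy numbers in all cells may account for the ratios over the 13 probes of the interval. Polyps 1, 2 and 3 lay within 0.0828 of those for 2, 4 and 3 copies against 3 in the normal DNA, numbers picked from the ratios. This stays open, because polyp 3 stood at -0.20 in the authors' deposited ratios, beyond the bound of 0.15. With normexp signals polyp 1 stood at -0.28. As the normexp offset draws ratios toward 0, that value cannot be set against -0.585 for 2 of 3 copies. Over the wider segment called in polyp 2 (76 probes), the main ratios were -0.11, 0.19 and 0.043 in polyps 1, 2 and 3. In polyps 1 and 2 these fall short of -0.585 and 0.415, the values for 2 and 4 copies against 3. On chromosome 2 these same copy numbers are argued against, since polyp 3 lay 0.2887 away from equal copies, and other whole numbers were not tested. Normexp signals gave -0.13 in polyp 3 and -0.27 in polyp 1 there, which for the same reason were not read as copy numbers. Whether these differences were inherited by the animals or arose in the polyps was not tested, as the labels do not say which animals the normal DNA came from.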
